A study of Mus musculus with 4 samples.

How the data were processed

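Total RNA from the gastric corpus of adult mice was labelled as biotinylated cDNA with the Affymetrix WT Plus kit, per the labels' protocols. There were 4 groups from 2 genotypes and 2 treatments (WT vehicle, WT metformin, AMPK KO vehicle and AMPK KO metformin), with 1 array in each, taken from the sample titles. The log2 expression values were deposited after robust multi-array averaging (RMA) in Partek, per the submitters' processing notes, and the log2 scale was read from the values, which lie between 0.77 and 14.02. The versions of both tools, their settings and the annotation build of the array are not given in the sources used here, so no coordinates are printed. Median values over all 41345 probe sets were 4.40 (WT vehicle), 4.47 (WT metformin), 4.55 (KO vehicle) and 4.46 (KO metformin). The number of arrays limits the precision of every value.

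Probe sets were named from the platform annotation, which pairs 23521 with 1 gene, 1814 with several genes and leaves 16010 unnamed here. Symbols were updated through gene identifiers in a RefSeq table of assembly GRCm38.p6, where 23328 of the 23521 were found, and that table also gave gene classes and the span of each gene as its length. Only probe sets with 1 gene were used. For 1082 genes with several probe sets the one with the highest mean over the 4 arrays stood for the gene, which left 22180 genes. Genes with a mean at or above the median of all genes (5.03 on the log2 scale) were kept, 11090 in all, of which 10555 were protein coding. Length was known for 11081 of them.

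Differences between 2 arrays are differences of log2 values, and a gene was counted as higher or lower at an absolute difference of 1 or more (2-fold). They have no p-value. Background levels per array are not given in the sources used here, and a difference from a value under 5.03 is not read as an exact fold. The difference of metformin responses is the KO response minus the WT response. Overlaps of counts are given beside the number expected for independent lists. Effects averaged over 2 arrays against 2 were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, genotype and treatment as terms, Benjamini-Hochberg adjusted p under 0.05). This leaves 1 residual degree of freedom, which also holds any real difference between the responses. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.

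The comparisons, the size rule, 40 gene lists and the rule for naming genes were fixed before the data were examined. The lists cover cell types of the corpus, cell types of neighbouring tissues that a sample could hold, immune and stromal cells, and metabolic, stress and control pathways. For each list with at least 4 genes past the filter (35 lists), the median difference was set against 10000 random lists of the same size drawn from 20 bins of mean expression. A list outside the central 95% is said to stand apart or to lie outside the random range, as a description of these arrays. With 35 lists of genes that vary independently, 1.8 would do so by chance in each comparison. Members of these lists may vary together, which would raise that number. In the WT response, the KO response, KO against WT under vehicle, the same under metformin, and the difference of responses, 9, 7, 7, 10 and 8 lists stood apart. In limma, list members were counted both over all genes tested and adjusted over the list alone.

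Named genes are the 10 highest and 10 lowest past 2-fold for the responses and the vehicle comparison, the 5 highest and 5 lowest for the other comparisons, those past the adjusted p in limma, up to 2 highest and 2 lowest members of each list discussed, and 23 genes chosen in advance. Predicted and clone-named genes, small RNA families and immunoglobulin segments were counted but not named by this rule. Where such genes appear, and where other genes are named in a count, they were chosen after their values were seen.

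On simulated arrays with the real gene means and the fitted spread (20 runs, 200 of 11090 genes changed between genotypes), limma found 2.55% of genes changed by 1 on the log2 scale, 93.85% of those changed by 2 and 99.85% of those changed by 3, with 5.5, 23.5 and 25.8 false calls on average. Among 400 random lists of 15 genes in the WT response, 23 stood apart with no added shift, 320 with a shift of 0.3 and 400 with 0.6. Such lists hold unrelated genes, so the 23 checks the calculation and not how often lists of related genes stand apart. Alternatives were no filter, a filter at the 75th percentile, cyclic loess between arrays, centring each array on its median, the mean of a gene's probe sets, a 1.5-fold rule, other variance models in limma, and other ways of summarising and matching lists. Chosen after seeing the data were a comparison of protein-coding genes alone and the removal of each array's trend on gene length (lowess, span 0.3) after cyclic loess among protein-coding genes only.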

Results

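Gene expression was measured with microarrays in the gastric corpus of adult mice after 14 days of daily intraperitoneal injections. The corpus is the acid-secreting part of the stomach, and its glands hold acid-secreting parietal cells, pepsinogen-secreting chief cells, mucous neck cells and surface pit cells. Wild-type mice (WT, C57BL/6) and mice lacking both catalytic subunits of the AMP-activated protein kinase in parietal cells (AMPK KO, Atp4b-cre with floxed Prkaa1 and Prkaa2) received metformin at 300 mg/kg or saline vehicle. Each of the 4 groups was measured on 1 array, so no difference between 2 arrays has a replicate check, and differences are given as sizes on the log2 scale. The KO mice were on a mixed background that included FVB, so genotype and strain background differed together. Between the WT vehicle and KO vehicle arrays the correlation over genes was the lowest of the 6 pairs (r = 0.905), and between the metformin arrays of both genotypes it was the highest (r = 0.971). How many animals contributed to each array is not given in the sources used here.

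The targeted genes were examined first. Prkaa1, which encodes the α1 catalytic subunit of AMPK, had log2 values of 9.46 on the WT vehicle array, 8.90 on the WT metformin array, 8.18 on the KO vehicle array and 8.66 on the KO metformin array. Prkaa2, which encodes the α2 subunit, had 8.90, 8.02, 7.19 and 7.52 on the same arrays. The difference of KO from WT under vehicle was -1.28 for Prkaa1 and -1.71 for Prkaa2, and under metformin it was -0.24 and -0.50. Both genes were lowest on the KO vehicle array. The RNA came from whole corpus, where cells other than parietal cells keep both genes, and the position of the probes relative to the floxed exons is not given in the sources used here.

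To find metformin targets in stomachs with mature parietal cells, the WT metformin array was compared with the WT vehicle array. Markers of parietal cells were lower with metformin, while genes of the mitochondrial respiratory chain and of the interferon response were higher. The 19 parietal cell genes had a median difference of -0.43, outside the range of random lists matched on expression (-0.31 to 0.11), and 3 of them lay above the median of all genes. Their lowest members were the water channel Aqp4 (-0.87) and the potassium channel Kcnj16 (-0.84), and the highest were creatine kinase Ckb (0.05) and carbonic anhydrase Car2 (-0.08). None of the 19 differed by 2-fold. On the KO vehicle array this list was also lower than on the WT vehicle array (median -0.42, inside its random range of -0.59 to 0.08). Both differences share the WT vehicle array, so they are not separate findings. The proton pump genes Atp4a and Atp4b had differences of -0.25 and -0.19, the pump-associated channel subunit Kcne2 -0.24, the nuclear receptor Esrrg -0.60 and the mitochondrial coactivator Ppargc1a -0.51.

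Oxidative phosphorylation genes had a median of 0.31 with metformin in WT (random lists -0.26 to 0.00), and 40 of 46 lay above the median of all genes. The highest were the cytochrome oxidase subunits Cox7a2 (1.07) and Cox7b (1.06), and the lowest were Uqcrc2 (-0.29) and Ndufs1 (-0.20). Short RNAs were also higher on this array, with a median difference of 1.13 over 59 small nucleolar RNA genes against -0.15 over protein-coding genes. Interferon response genes had a median of 0.59, with all 9 above the median of all genes, led by the antiviral enzyme Oas2 (1.08) and the immunoproteasome subunit Psmb8 (0.65). The lowest members were Cxcl9 (-0.06) and Gbp3 (0.13). Circadian clock genes had a median of -0.41, with Dbp (-1.21) and Nr1d1 (-1.21) lowest and Nfil3 (0.57) and Cry1 (0.50) highest. The median of the mast cell genes was -0.56, from Cpa3 (-0.88) and Kit (-0.83) to Mcpt2 (1.12). Squamous epithelial genes had a median of 0.59, led by Krt13 (0.71) and Krt10 (0.62), with Sprr1a (0.25) and Sbsn (0.27) lowest. Some of these 5 pass the filter through their level on the KO metformin array, and over all 16 measured members the median was 0.26 (random lists -0.14 to 0.25), with Krt4, Krt6a, Krt15 and Trp63 negative. Smooth muscle (0.13), fibroblast (0.10) and skeletal muscle (0.28) lists lay just above their random ranges, and these calls and that of the mast cell list were each lost under an alternative.

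Of 11090 genes, 86 were at least 2-fold higher and 103 at least 2-fold lower with metformin in WT. The 10 lowest were the transcriptional repressors Bcl6 (-1.85) and Zbtb16 (-1.79), the neuropeptide receptor Vipr2 (-1.74), Lrrc31 (-1.53), Ap3s2 (-1.47), the kinase Stk32b (-1.45), the MAP kinase phosphatase Dusp1 (-1.43), Zscan26 (-1.43), the mitochondrial carrier Slc25a21 (-1.42) and Abitram (-1.41). The 10 highest were Erdr1 (2.30), the RNase P RNA gene Rprl2 (1.87), Ptcd3 (1.79), Rps12-ps24 (1.74), Mettl7a3 (1.53), the mitochondrial ribosomal gene Mrps16 (1.52), Snhg17 (1.44), Plac8 (1.43), S100a7l2 (1.41) and Wdyhv1 (1.38). A further probe set of Ptcd3 gave -0.22. The balance of directions moved with the scaling, from 54.5% lower as deposited to 40.4% after cyclic loess and 69.3% with each array centred on its median, and 74.6% of the 134 protein-coding genes past 2-fold were lower.

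**Figure D1:**
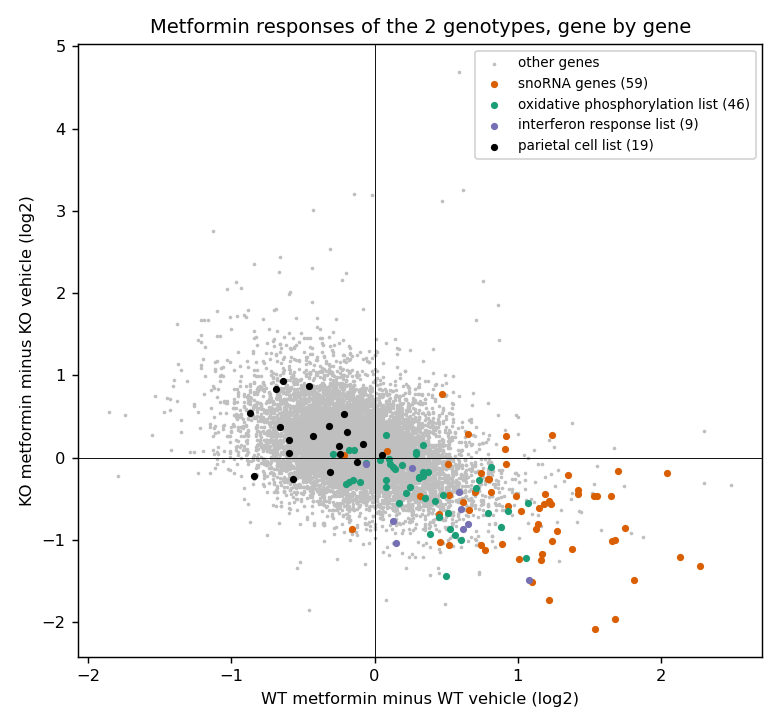
Each point is 1 gene past the expression filter, with its metformin minus vehicle difference (log2) in WT on the x axis and in AMPK KO on the y axis. The 59 small nucleolar RNA genes lie mostly at the lower right (medians 1.13 and -0.56) with many of the 46 oxidative phosphorylation genes (medians 0.31 and -0.28), and the 19 parietal cell genes lie mostly to the left of 0 (medians -0.43 and 0.21).

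To find responses in progenitor and non-parietal cells, in mice that the submitters describe as having fewer and less mature parietal cells, the KO metformin array was compared with the KO vehicle array. Genes of cornified squamous epithelium were among the highest. Krtdap, a keratinocyte differentiation gene, was higher with metformin by 4.69, from a vehicle value of 4.43 that lies under the filter value, so no fold is given. The suprabasal keratin Krt10 was 9.5-fold higher (3.25) and the cornified envelope gene Cnfn 8.7-fold (3.12). The squamous list had a median of 1.67 (random lists -0.34 to 0.48), and 4 of its 5 members past the filter were at least 2-fold higher, with Sbsn (0.53) and Sprr1a (1.31) lowest. Krtdap and Krt13 were under the filter value on all other arrays and pass it only through the KO metformin array. Sbsn was at 4.55 (WT vehicle), 4.82 (WT metformin) and 5.23 (KO vehicle), and it too passes only with the KO metformin array (5.76) in its mean. The 5 members were thus partly chosen by the values compared here. Of all 16 measured members, 14 were highest on the KO metformin array. Forestomach, the squamous part of the mouse stomach that borders the corpus, carries these genes too.

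Mucous neck cell genes were also higher in KO with metformin (median 0.73, random lists -0.22 to 0.57), led by the gland mucin Muc6 (1.22) and the glycosyltransferase A4gnt (1.19), with Gkn3 at 0.96, Bpifb1 (0.02) and Tff2 (-0.19) lowest. Genes of cholesterol and fatty acid synthesis had a median of 0.49 (random lists -0.06 to 0.40), and 3 of 16 were at least 2-fold higher. These were the fatty acid elongase Elovl6 (2.54), the sterol regulator Srebf2 (1.02) and the desaturase Scd1 (1.01), while Fdps (-0.05) and Hmgcs1 (-0.01) were lowest. In KO against WT this list had a median of -0.54 under vehicle and 0.17 under metformin. Both medians lay inside their random ranges, while both means (-0.63 and 0.21) lay outside theirs. The KO response and the vehicle difference share the KO vehicle array, so they are not separate findings. Smooth muscle genes had a median of 0.49, with Des (1.32) and Cnn1 (1.02) highest and Tagln (-0.07) and Mylk (0.03) lowest. With the trend on gene length removed, which was done after cyclic loess and among protein-coding genes only, the smooth muscle median was 0.27 and inside its random range.

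Oxidative phosphorylation and interferon response genes were lower in KO with metformin. The respiratory chain list had a median of -0.28 (random lists 0.00 to 0.28), with 44 of 46 below the median of all genes and Ndufa1 (-1.44) and Cox7b (-1.22) lowest, against Atp5d (0.28) and Cyc1 (0.15) as the highest. Small nucleolar RNA genes had a median of -0.56 on the same comparison. All 9 interferon response genes lay below the median of all genes (list median -0.77), from Oas2 (-1.48) and Oasl2 (-1.04) to Cxcl9 (-0.08) and Usp18 (-0.13). Circadian clock genes had a median of 0.33, with Dbp (1.13) and Nr1d1 (1.09) highest and Nfil3 (-0.19) and Nr1d2 (-0.16) lowest, and their call was lost with the trend on gene length removed (0.21), with all measured members (0.33) and with unmatched random lists (0.33). Parietal cell genes had a median of 0.21, inside the random range (-0.08 to 0.38), with Atp4a at 0.14, Atp4b at 0.31, Kcne2 at 0.04, Esrrg at 0.21 and Ppargc1a at 0.02.

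In KO, 271 genes were at least 2-fold higher and 68 at least 2-fold lower with metformin. Beside Krtdap, Krt10 and Cnfn, the highest were Ly6g6c (3.19), the incretin receptor Glp1r (2.75), Elovl6 (2.54), the galectin Lgals12 (2.44), Trp53i11 (2.31), Dapp1 (2.26) and Dthd1 (2.24). The lowest were Ifit1bl1 (-1.78), the class I histocompatibility gene H2-Q10 (-1.73), Oas2 (-1.48), the complex I subunit Ndufa1 (-1.44), Fmc1 (-1.42), the antiviral tether Bst2 (-1.40), Hecw1 (-1.39), carbonic anhydrase Car3 (-1.34), Zfp607a (-1.34) and the antiviral helicase Ddx60 (-1.29). As deposited, 20.1% of the differences past 2-fold were lower, against 32.5% after cyclic loess, 10.2% after centring and 39.1% with no expression filter.

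The genotypes were compared under vehicle to describe the stomach without AMPK in parietal cells. Single genes of plasma cells, mast cell genes and interferon response genes were higher in KO, and smooth muscle and endothelial genes were lower. The highest were Chil4, a chitinase-like protein (4.07), the mast cell protease Mcpt2 (3.39), the immunoglobulin joining chain Jchain (3.07) and, further down, the epithelial immunoglobulin receptor Pigr (2.05). All 4 lie under the filter value on the WT vehicle array (at most 4.88), so no fold is given. Of 3 plasma cell genes past the filter, too few to set against random lists, the immunoglobulin heavy chain gene Ighm was also higher (3.75) and Derl3 was not (-0.49). The mast cell list had a median of 1.07 (random lists -0.82 to 0.31), although Kit was lower (-1.61). Interferon response genes had a median of 0.84 (random lists -0.57 to 0.22), from Oas2 (1.82) and Ifit1 (1.45) to Cxcl9 (0.02) and Usp18 (0.18).

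Oxidative phosphorylation genes were higher in KO under vehicle, with a median of 0.43 (random lists -0.47 to -0.08) and 43 of 46 above the median of all genes. Cox7b (1.99) and Ndufa1 (1.54) were highest and Uqcrc2 (-0.62) and Atp5d (-0.55) lowest, and small nucleolar RNA genes had a median of 1.13. Squamous genes had a median of 0.68, from Krt13 (0.99) and Krt10 (0.78) to Sprr1a (-0.26). Smooth muscle genes were lower (median -0.82, random lists -0.64 to 0.11), 5 of 13 by at least 2-fold, with Cnn1 (-1.47) and Des (-1.36) lowest and Tagln (0.25) and Tpm2 (-0.28) highest. Endothelial genes had a median of -0.65, from Plvap (-1.64) and Tek (-0.97) to Emcn (-0.25) and Flt1 (-0.36), and lay inside the random range with the trend on gene length removed (-0.29). Clock genes had a median of 0.28 but a mean of -0.06, since Arntl (-2.35) and Npas2 (-1.60) were far below and Per3 (1.61) and Ciart (1.09) above.

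Parietal cell genes had a median of -0.42 in KO under vehicle, inside the range of random lists (-0.59 to 0.08), since the median of all genes was -0.22. Their mean (-0.58) lay outside the range of means of random lists, so the call depends on the summary. At least 2-fold lower were 5 of the 19, with Aqp4 (-1.54) and the sodium-proton exchanger Slc9a4 (-1.44) lowest and Esrrb (0.16) and Slc4a2 (0.15) highest. Atp4a (-0.42), Atp4b (-0.43), Kcne2 (-0.35), Esrrg (-0.38) and Ppargc1a (-0.80) had smaller differences. Chief cell genes had a median of -0.02, with Bhlha15 at 0.51, Cblif at -0.23 and Pgc at 0.02. Mucous neck cell genes differed among themselves, with Muc6 at -1.05, Tff2 at 0.89 and Gkn3 at 0.21.

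Past 2-fold, 256 genes were higher and 900 lower in KO under vehicle. The lowest were the phosphodiesterase Pde7b (-2.92), catalase (Cat, -2.90), the glycosyltransferase B4galnt2 (-2.80), Glp1r (-2.75), the antigen-presenting molecule Mr1 (-2.75), the ubiquinone synthesis gene Coq5 (-2.71), Elovl6 (-2.65), Adgrd1 (-2.60), Vipr2 (-2.57) and Lgals12 (-2.55). The complement gene C7 (-2.70) belongs among them by value, but the naming rule took its symbol for a clone name. Among the highest were also Erdr1 (2.71), Ifit1bl1 (2.48), Cnbd2 (2.24), Atp5e (2.10), Cox7b (1.99) and Rprl2 (1.92). The share that was lower depended on the scaling, at 77.9% as deposited, 60.4% after cyclic loess and 89.5% after centring, and the median of all genes moved with it, from -0.22 to -0.07 and -0.37. With no expression filter it was 62.8%. Of the 1156 genes past 2-fold as deposited, 1038 were protein coding, and 931 genes passed after cyclic loess. With cyclic loess, protein-coding genes alone and the length trend removed together, 669 passed.

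**Figure D2:**
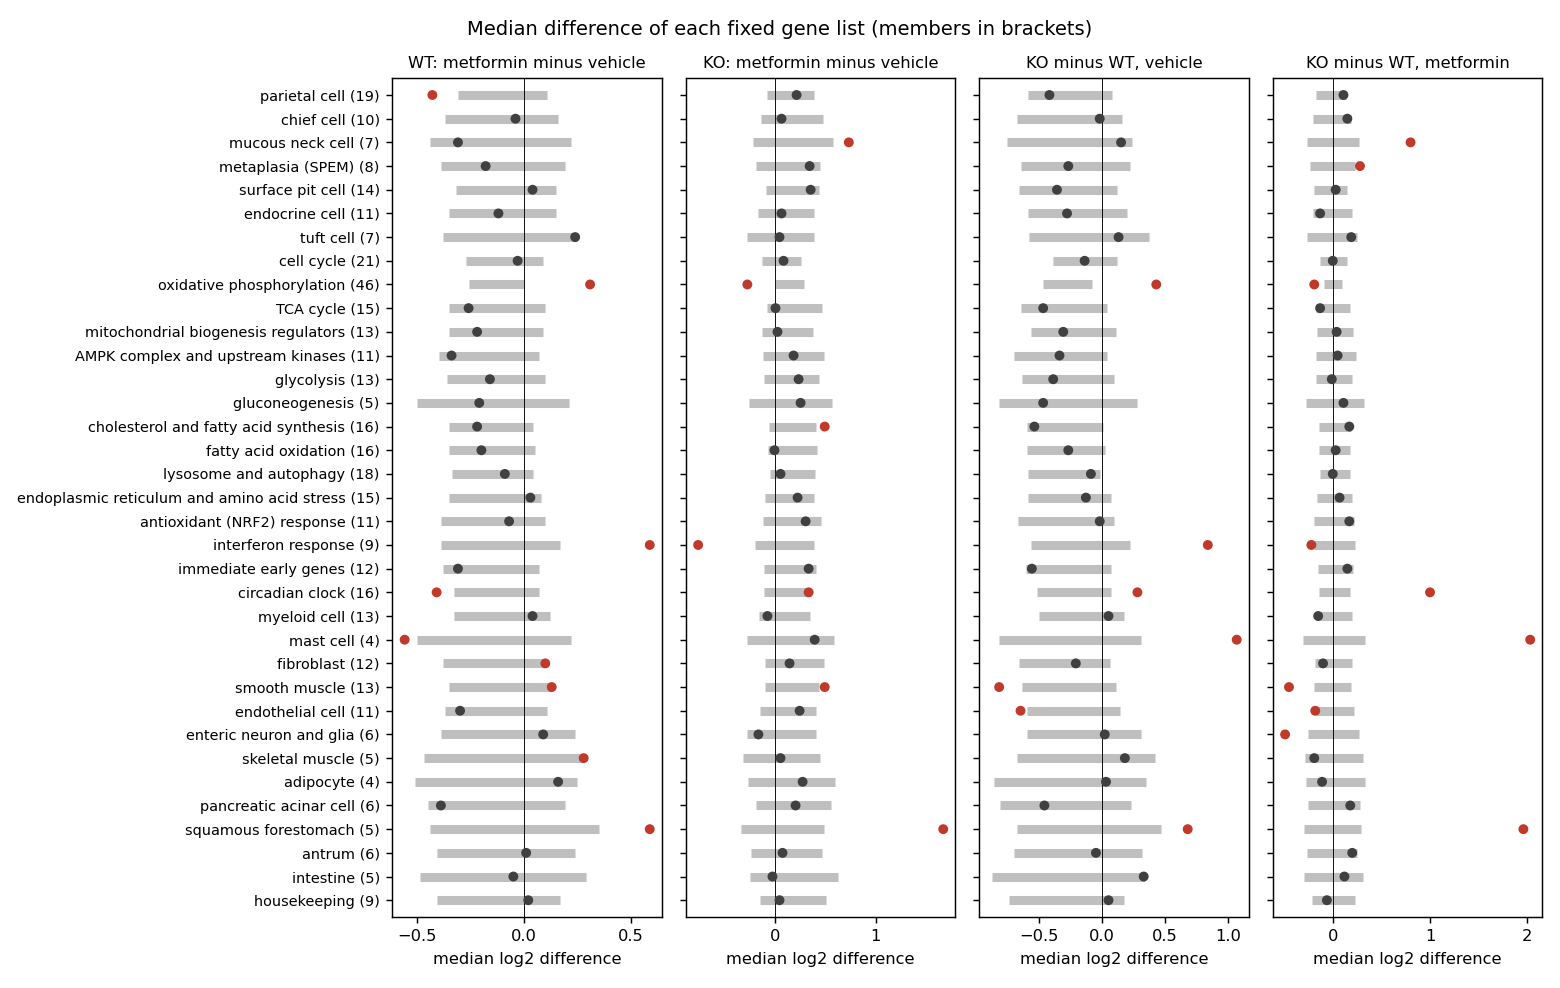
Each dot is the median log2 difference of 1 gene list in 1 of the 4 comparisons, and the grey bar is the central 95% of 10000 random lists of the same size matched on mean expression. Red dots lie outside their bar, as the oxidative phosphorylation list does in all 4 panels (0.31, -0.28, 0.43 and -0.19).

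Under metformin, the genotypes differed in fewer genes, 59 higher and 43 lower in KO past 2-fold. The highest were Krtdap (4.61), Cnfn (3.66), Krt10 (3.41), Chil4 (3.08) and Jchain (2.89). The lowest were the clock activator Arntl (-1.74), Car3 (-1.44), Ifi27l2b (-1.36), the signalling regulator Rgs13 (-1.34) and the small nucleolar RNA AF357355 (-1.28). Circadian clock genes had a median of 1.0 (random lists -0.14 to 0.18), with 8 of 16 at least 2-fold higher and 1 lower. Dbp (2.06) and Per3 (1.75) were highest and Arntl and Npas2 (-0.75) lowest. Mast cell genes had a median of 2.03, with Cpa3 (2.21) and Tpsb2 (2.10) highest, Mcpt2 at 1.96 and Kit at -0.31, and squamous genes 1.96, with Sprr1a (0.79) and Sbsn (0.94) lowest. Over all 16 measured squamous genes the median was 1.02.

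Mucous neck cell genes were higher in KO under metformin (median 0.80, random lists -0.26 to 0.27), with Gkn3 (1.27) and the water channel Aqp5 (1.05) highest and Tff2 (-0.28) and A4gnt (0.74) lowest, and Muc6 at 0.80. Genes of spasmolytic polypeptide-expressing metaplasia, a wound response of the corpus glands, had a median of 0.28 (random lists -0.23 to 0.23), with Dmbt1 (1.99) and Sox9 (0.78) highest, Cd44 at 0.76, and Mal2 (-0.17) and Olfm4 (0.00) lowest. Lower in KO were smooth muscle genes (-0.45), with Cnn1 (-0.64) and Synpo2 (-0.64) lowest and Smtn (0.22) highest, and enteric neuron and glia genes (-0.49), with Vip (-0.96) and Ret (-0.71) lowest and Sox10 (0.06) and Snap25 (-0.01) highest. Oxidative phosphorylation genes (-0.19), interferon response genes (-0.22) and endothelial genes (-0.18) were lower too, as were small nucleolar RNA genes (-0.39). The endothelial call was lost after cyclic loess, where the value was the same (-0.18) and lay just inside the random range (-0.19 to 0.20), with means (-0.11) and with the length trend removed (-0.17). The call was lost for enteric neuron and glia genes with all measured members (-0.12). Parietal cell genes had a median of 0.11, inside the random range, with Atp4a at -0.03, Atp4b at 0.07 and Esrrg at 0.43.

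Averaged over both treatments, 5 genes differed between genotypes in limma's moderated test of 2 KO against 2 WT arrays (Benjamini-Hochberg adjusted p). Chil4 rose by 3.57 (SE 0.34, adjusted p = 0.0222), Jchain by 2.98 (SE 0.30, adjusted p = 0.0222), and the immunoglobulin segments Igkv5-43 by 2.55 (SE 0.30, adjusted p = 0.0397) and Igkj1 by 2.47 (SE 0.30, adjusted p = 0.0397). Gm12888, a predicted protein-coding gene, fell by 3.66 (SE 0.41, adjusted p = 0.0348). Each difference had the same direction under both treatments. The residual of the fit is the disagreement between the treatments, so the test favours such genes and the shared direction is no separate support. With no expression filter Chil4 and Jchain still passed and the other 3 did not, and with the 75th percentile filter none of the 5 did, of which only Gm12888 and Igkv5-43 were tested there. Adjusted over the list alone, 8 of 16 clock genes passed (Per3, Cry1, Nr1d2, Tef, Ciart and Bhlhe41 higher, Arntl and Npas2 lower), 4 of 4 mast cell genes (Cpa3, Mcpt2 and Tpsb2 higher, Kit lower), 4 of 5 squamous genes, 2 of 3 plasma cell genes (Jchain and Ighm) and the metaplasia gene Dmbt1. Over all genes tested, 1 of these 19 list members passed, Jchain. The squamous passes of Krtdap and Krt10 rest mainly on the KO metformin array (9.13 and 8.69, against 4.43 and 5.44 on the KO vehicle array). That array also decides in part which squamous genes pass the filter. The fit leaves 1 residual degree of freedom, and on simulated arrays it found 2.55% of genes changed by 1 on the log2 scale and 93.85% of those changed by 2. It also made 5.5 and 23.5 false calls on average in those simulations, and about 3 for an effect that was absent. The simulated errors were independent, while the residual here also holds opposed responses.

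No gene passed for the effect of metformin averaged over both genotypes with limma. An unadjusted p under 0.05 was found for 32 genes, far under a share of 0.05 of the 11090 tested. The residual of this fit is the difference between the responses, which were opposed, so the test erred towards no calls. The absence of calls is therefore not read as absence of an effect of metformin. Adjusted over the list alone, Krtdap, Krt10 and Krt13 of the squamous list passed. For Krtdap and Krt10 these averages come mainly from the KO metformin array. Krtdap was at 9.13 there and at most 4.51 elsewhere, and Krt10 at 8.69 against at most 5.44. At 2-fold, no gene was higher in both genotypes or lower in both, against 2.1 and 0.63 expected for independent lists. Opposite directions were found for 18 genes higher in WT and lower in KO (0.53 expected) and for 28 lower in WT and higher in KO (2.52 expected). Of the 18, 4 were protein coding, and of the 28, 27 were. With the trend on gene length removed the counts among protein-coding genes were 6 and 7, after cyclic loess the 18 and 28 became 24 and 14, and after centring 13 and 43. Across the 11090 genes the responses had a Pearson r of -0.40 and a Spearman rho of -0.37. The responses share no array, and genes are not independent replicates.

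The difference of the responses, KO minus WT, was taken to separate targets in mature parietal cells from those in other cells, and has no test with 4 arrays in 4 groups. It also equals the genotype difference under metformin minus that under vehicle, so it is not independent of those comparisons. Mucous neck cell genes (median 1.04, random lists -0.31 to 0.89) responded higher in KO, with A4gnt (2.22) and Muc6 (1.85) highest and Tff2 (-1.17) and Bpifb1 (0.00) lowest. Squamous genes (1.05), immediate early genes (0.75) and mast cell genes (0.95) also did. Among immediate early genes Dusp1 (2.0) and Nr4a1 (1.56) were highest and Junb (-0.44) and Ier3 (-0.40) lowest. Parietal cell genes had a median of 0.67 (random lists -0.09 to 0.63), with Slc9a4 (1.56) and Kcnj15 (1.52) highest and Ckb (-0.02) and Slc4a2 (0.07) lowest, and 0.26 with the trend on gene length removed, inside the random range. Interferon response (-1.20), oxidative phosphorylation (-0.55) and myeloid cell genes (-0.25) responded lower in KO, and small nucleolar RNA genes had a median of -1.75, with 2 of 59 above 0. The calls were lost for mucous neck cell genes with means in place of medians (0.81, random lists -0.33 to 0.84), for mast cell genes after cyclic loess (0.73), with means (0.51) and with all measured members (0.13), for immediate early genes with all measured members (0.57) and for myeloid cell genes with the trend on gene length removed (-0.12).

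By gene, the highest differences of responses were Krtdap (4.10), Glp1r (3.88), Ly6g6c (3.21), Coq5 (3.11) and Lgals12 (3.10). The lowest were Rprl2 (-2.83), Ptcd3 (-2.71), Oas2 (-2.55), the ATP synthase subunit Atp5e (-2.55) and Tlcd1 (-2.34), with other probe sets of Ptcd3 and Tlcd1 at 0.38 and 1.02. In all, 1241 genes were past 2-fold higher and 400 lower. As deposited 24.4% were lower, against 41.9% after cyclic loess, 13.0% after centring and 44.6% with no expression filter.

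**Figure D3:**
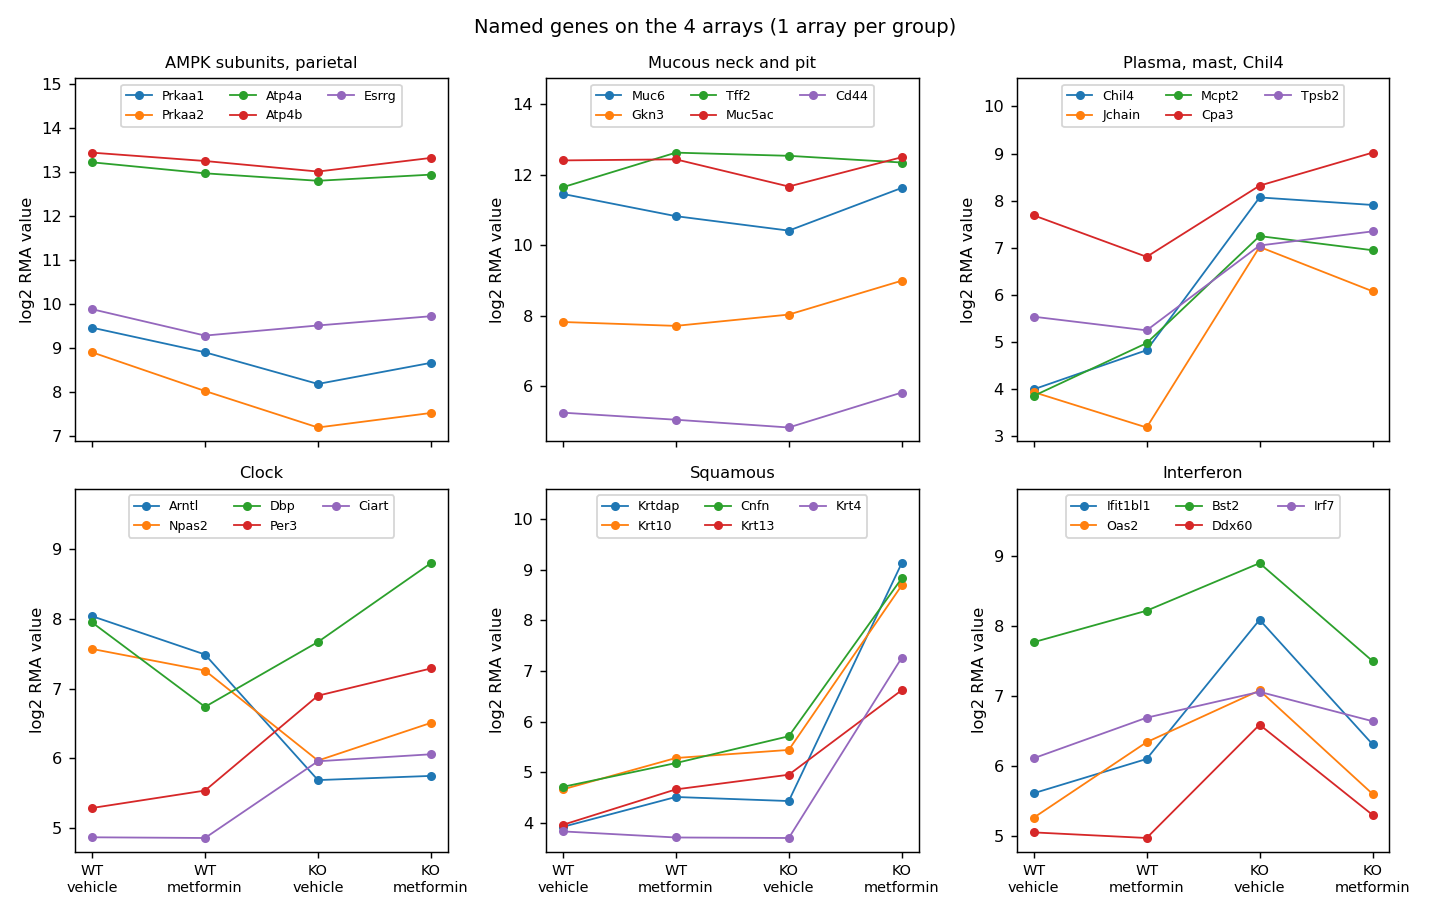
Lines join the log2 values of single genes on the 4 arrays, in 6 panels by gene group. Krtdap is at 9.13 on the KO metformin array and at most 4.51 elsewhere, Chil4 is at 8.07 and 7.91 on the KO arrays against at most 4.83 on the WT arrays, and Arntl is lower on both KO arrays (5.69 and 5.75).

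Lists of chief, surface pit, endocrine and tuft cells stayed inside their random ranges in all comparisons, except that tuft cell genes lay above theirs in the WT response with all measured members (0.23) and with unmatched random lists (0.24). Chief cell genes had medians of -0.04 for the WT response and 0.06 for the KO response, with Pgc at -0.01 and -0.03, Cblif at -0.17 and 0.15 and Bhlha15 at -0.04 and -0.34. Surface pit cell genes had medians of 0.04 and 0.35 for the same responses, with Muc5ac at 0.04 and 0.83, Gkn2 at 0.06 and 0.06 and Tff1 at 0.32 and 0.00. Endocrine cell genes had medians of -0.12 and 0.06, with the histamine synthesis gene Hdc at -0.46 and 0.24, Ghrl at -0.12 and 0.14, Sst at -0.02 and -0.19 and Gast at 0.20 and 0.02. Tuft cell genes had medians of 0.24 and 0.04. Among genes fixed in advance, Muc6 was at -0.63 and 1.22, Tff2 at 0.98 and -0.19, Gkn3 at -0.10 and 0.96, Cd44 at -0.19 and 0.99, the transcription factor Klf4 at 0.18 and 0.75 and the proliferation marker Mki67 at -0.17 and 0.63. Cell cycle genes as a list had medians of -0.03 and 0.08.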

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

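The tests of squamous tissue, of time of day and of AMPK loss below, the shift by a constant and the removal of the trend on gene length, were chosen after the results were seen. Differences between the genotypes' metformin responses were not tested, since each response rests on 1 array against 1.

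Metformin responses of several gene groups ran in opposite directions in the genotypes. The median of the oxidative phosphorylation genes was 0.31 in WT and -0.28 in KO, a difference of -0.59 between the medians. For interferon response genes it was 0.59 and -0.77, a difference of -1.35, and for circadian clock genes -0.41 and 0.33, a difference of 0.74. Taken gene by gene, the median difference of responses of the clock genes was 0.53, inside its random range (-0.09 to 0.59), and their KO call was lost under 3 alternatives. Their mean difference of responses (0.76) lay outside the range of means of random lists (-0.10 to 0.58), so the former call depends on the summary. For each gene the difference of responses equals the genotype difference under metformin minus that under vehicle. For oxidative phosphorylation genes the vehicle median was 0.43 against -0.19 under metformin, and for interferon response genes 0.84 against -0.22. Their opposite responses and their vehicle differences are therefore not separate findings. For clock genes the list median of the genotype difference was larger under metformin (1.0 against 0.28), but it mixes genes that ran in opposite directions. The median of 9 output genes was larger under metformin (1.23 against 0.71 under vehicle). That of 4 activator genes was further from 0 under vehicle (-1.32 against -0.51 under metformin). Among the genes named by rule, those past 2-fold in opposite directions were the incretin receptor Glp1r (-1.13 in WT and 2.75 in KO, difference 3.88), the antiviral enzyme Oas2 (1.08 and -1.48, difference -2.55), the ATP synthase subunit Atp5e (1.29 and -1.26, difference -2.55), Tlcd1 (1.18 and -1.16, difference -2.34, with another probe set at 1.02), Cox7b (1.06 and -1.22, difference -2.27), Dbp (-1.21 and 1.13, difference 2.34), Nr1d1 (-1.21 and 1.09, difference 2.29) and A4gnt (-1.03 and 1.19, difference 2.22). Mr1 (-1.10 and 1.78, difference 2.88), Cat (-1.21 and 1.49, difference 2.70), Pde7b (-1.23 and 1.43, difference 2.66) and Adgrd1 (-1.21 and 1.41, difference 2.62) did so too, but they were named for being lowest in KO against WT under vehicle, and those arrays are also the vehicle arrays of both responses. Glp1r, Atp5e and Cox7b were also among the genes named under vehicle. Glp1r, Oas2, Atp5e and Tlcd1 were named for their difference of responses itself. The opposition of genes chosen in these ways is no separate support for opposite responses.

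Across genes the responses were opposed as well (r = -0.40), with respiratory chain genes and small nucleolar RNA genes at one end. An intensity-dependent difference between arrays is argued against as the source of the correlation, since r was -0.39 after cyclic loess. Whether it made the excess of lower genes in KO under vehicle cannot be told, since their share went from 77.9% to 60.4% after cyclic loess and to 60.3% when all differences were shifted by 1 constant to the same median. A difference between arrays in the yield of short against long transcripts is a candidate explanation that the values meet: gene length had a Spearman rho of -0.33 with the WT response and 0.17 with the KO response, and the small nucleolar RNA medians (1.13 and -0.56) were opposite in sign to the protein-coding medians (-0.15 and 0.12). Gene span is a weak stand-in for transcript length, and r was still -0.34 with its trend removed after cyclic loess among protein-coding genes, with medians of 0.31 in WT and -0.45 in KO for respiratory chain genes and 0.54 and -0.80 for interferon response genes, so length in this form does not account for the whole. Opposite responses of the tissue to metformin with and without AMPK in parietal cells stay open and untested.

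Squamous genes were highest on the KO metformin array for 14 of the 16 list members measured (87.5%), the exceptions being Krt14 (4.29) and Krt15 (3.87), 2 keratins of basal squamous cells, but 11 of the 16 have means under the filter value and some gaps are small, as for Ivl (3.80 against 3.69) and Trp63 (3.60 against 3.38). Krtdap (9.13), Krt10 (8.69), Krt4 (7.26) and Krt1 (7.21) stood far above the other arrays there. Forestomach tissue in that sample is a candidate source, and 4 of the 5 brightest members were at least 1 above the mean of the other arrays, with Sbsn at 0.89 above. These 5 are the members past the filter, ranked by a mean that includes the KO metformin array, so they were partly chosen by that array. A squamous change of the corpus with metformin in KO, and a larger share of the squamous border in the dissected piece, cannot be told apart with 1 array and RNA from whole tissue.

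Clock genes differed between the genotypes with opposite arms. Under metformin the median of 9 output and repressor genes was 1.23 and that of 4 genes of the activator phase (Arntl, Clock, Npas2 and Nfil3) -0.51, and under vehicle the medians were 0.71 and -1.32, as different times of day at collection could give. Under metformin all 9 output genes lay above the median of all genes and all 4 activator genes below. Under vehicle 6 of 9 and 3 of 4 did. The arms leave out the remaining list members, among them Cry1, which was higher in KO over both treatments. Loss of AMPK in parietal cells may also shift the clock (list median 1.0 under metformin), and it cannot be told apart from collection time, which is not given in the sources used here. Strain background differed together with genotype, so it cannot be told apart from them either. Arntl was lower on both KO arrays, but other members differed between treatments, with 2 of 16 higher and 4 lower past 2-fold under vehicle against 8 and 1 under metformin, and Dbp at -0.29 and 2.06.

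Probe sets outside the named genes also differed. Of 4283 unnamed probe sets past the filter value, 56 were at least 2-fold higher in KO under both treatments and 10 lower, and of 798 that name several genes, 5 were higher and 1 lower.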

How the results depend on the processing

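The comparison of protein-coding genes alone and the removal of the length trend were chosen after the data were seen. After cyclic loess, with probe sets averaged and with protein-coding genes alone, the totals past 2-fold stayed within 1.5 times the reported ones, but counts by direction did not. After cyclic loess 562 genes in place of 900 were lower in KO under vehicle and 768 in place of 1241 higher in the difference of responses, and among protein-coding genes 34 in place of 86 were higher in the WT response. The WT response went from more lower (86 higher and 103 lower) to more higher after cyclic loess (102 and 69) and with the 75th percentile filter (66 and 59), and KO against WT under metformin from 59 higher and 43 lower to 18 and 25 with that filter. None of the 80 named differences changed direction after cyclic loess, after centring or with probe sets averaged, the 3 alternatives run for them. The r of 0.02 between the genotype differences lay between -0.02 and 0.05. The clock list under vehicle had a median of 0.28 but a mean of -0.06. Other counts follow in the order WT response, KO response, KO against WT under vehicle, under metformin, and difference of responses. The 75th percentile filter, which tests fewer genes, gave 125, 221, 716, 43 and 983, the 1.5-fold rule 1401, 1792, 3535, 641 and 4234, and cyclic loess, protein-coding genes alone and removal of the length trend together 83, 210, 669, 67 and 992, against 134, 294, 1038, 71 and 1474 for protein-coding genes alone. With no filter, which tests more genes, the counts were 298, 557, 1606, 216 and 2626, with 597 in place of 256 higher in KO under vehicle, and 218 in place of 68 lower in the KO response and 1172 in place of 400 in the difference. For limma's genotype effect, 3 genes passed with no filter (Chil4, Jchain and Mcpt1), 0 with the 75th percentile filter (148 at an unadjusted p under 0.05), 8 with an intensity trend, and 40 with centred arrays (21 higher and 19 lower), and the 5 reported genes were among these 8 and 40. With centred arrays 3 genes passed for metformin (Krtdap, Krt10 and Cnfn). In the centred fit limma drew the variance of all genes to 1 shared value. The correlation of responses ranged from -0.45 to -0.34. Of 175 list results 41 stood apart, against 36 to 43 under the alternatives, with 172 on the same side after cyclic loess, 175 after centring, 166 with the length trend removed, 163 with all measured members, 161 with means and 170 with unmatched random lists. With means 8 calls were gained and 6 lost. The gained calls include the clock and lipid synthesis lists in the difference of responses. Centring shifts all genes of an array alike, so it could change neither the list calls nor the correlation of responses, and its 175 is no check. All 80 named differences kept 2-fold after cyclic loess and after centring, and 71 did with probe sets averaged. Beyond the terms for genotype and treatment in limma, no pairing of samples could be used. Each group has 1 array, so no replicate could be left out. Background levels per array are not given in the sources used here, so genes with a mean under 5.03 were left out of the counts past 2-fold, while results over all measured list members include them.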

Other observations

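Metabolic lists other than the respiratory chain stayed inside their random ranges in both metformin responses, apart from lipid synthesis in KO and, with all measured members, antioxidant genes in KO (0.37). In WT the medians were -0.26 for the tricarboxylic acid cycle, -0.22 for regulators of mitochondrial biogenesis, -0.34 for the AMPK complex and its upstream kinases, -0.16 for glycolysis, -0.21 for gluconeogenesis, -0.22 for cholesterol and fatty acid synthesis and -0.20 for fatty acid oxidation, beside a median of -0.14 over all genes. In KO they were 0.00, 0.02, 0.18, 0.23, 0.25, 0.49 and -0.01, beside 0.11 over all genes. Tricarboxylic acid cycle genes thus did not share the direction of the respiratory chain genes in WT, with citrate synthase (Cs) at -0.39 and Idh3a at -0.64. Lysosome and autophagy genes had medians of -0.09 and 0.05, endoplasmic reticulum and amino acid stress genes 0.03 and 0.22, antioxidant genes -0.07 and 0.30, and housekeeping genes 0.02 and 0.04.

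In KO against WT, 23 genes were at least 2-fold higher under both treatments (1.36 expected for independent lists) and 10 lower (3.49 expected). Opposite directions were found for 8 genes higher under vehicle and lower under metformin (0.99 expected) and 5 lower and then higher (4.79 expected). Among protein-coding genes the counts were 13 and 10, mostly since immunoglobulin segments are not in that class. The comparisons share no array, and their differences had an r of 0.02 across all genes. The 23 were picked out after their values were seen and include Chil4, Jchain, Ighm, 7 immunoglobulin kappa segments, the mast cell proteases Mcpt2 and Tpsb2, the type 2 immunity gene Retnla (1.09 under vehicle and 1.12 under metformin), the goblet cell gene Clca1 (1.52 and 1.03), Pigr (2.05 and 1.16), and the heme synthesis gene Alad (1.32 and 1.22). Among the 10 lower were Gm12888 (-4.48 and -2.83), Arntl, Ifi27l2b (-1.78 and -1.36), the complement gene C7 (-2.70 and -1.22), the neuropeptide receptor Adcyap1r1 (-2.09 and -1.14) and the esterase Ces2a (-2.38 and -1.10). Mcpt1, under the expression filter on average, was at 2.88 and 3.38 on the WT arrays and at 6.37 and 6.51 on the KO arrays. The KO mice carried FVB background, so strain and genotype are not separated in these genes.

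Markers of neighbouring tissues other than squamous epithelium stayed inside their random ranges in both responses, with the exception of skeletal muscle in WT and, with all measured members, adipocyte genes in WT (0.29). For the WT and the KO response, pancreatic acinar genes had medians of -0.39 and 0.20, antrum genes 0.01 and 0.07, intestine genes -0.05 and -0.03, and adipocyte genes 0.16 and 0.27. Too few members passed the filter to set T and NK cell genes (2), Y-linked genes (3), metformin transporters (1) or erythrocyte genes (0) against random lists. The Y-linked gene Eif2s3y was measured on all arrays (7.73, 7.38, 7.82 and 7.39).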
